A study of Homo sapiens with 4 samples.

How the data were processed

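KYSE410 cells received PBS, TNFα, IL1β or LPS for 24 h, and total RNA was copied to cDNA, labelled with Cy3 using the one-colour NimbleGen kit and hybridised to 1 array per condition, per the labels' protocols. The doses are not given in the sources used here. The deposited values are RMA intensity on a linear scale, 1 per probe set, per the file headers and names (RMA is robust multi-array averaging, which in its usual form corrects background, equalises the distributions of arrays and combines the probes of a set). The software, its version and its settings are not given in the sources used here. A probe set usually had 3 probes. The authors also deposited a series value table, and its intensity values were identical to the per-array ones for all 45033 probe sets on each of the 4 arrays. The per-array tables hold in addition a control set of 5000 random-sequence probes, with intensities of 54.1 for PBS, 55.8 for TNFα, 56.1 for IL1β and 56.4 for LPS.

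Equalised distributions remove any change of total RNA shared by most genes, so differences are relative to the bulk of genes. The median of all genes differed by less than 0.05 log2 between any pair of arrays.

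Probe sets carry transcript accessions, which were matched without versions to the RefSeq table of assembly GRCh38.p14, used for names only. Of 45033 probe sets 18866 (41.9%) matched 1 gene symbol and 26167 did not. The matched sets stand for 17185 genes, 1349 of which had 2 or more probe sets. A gene took the values of its probe set with the highest mean log2 intensity over the 4 arrays. No coordinates are given because no genome build is stated for the arrays.

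Each comparison is a difference of log2 intensities between 2 arrays. With 1 array per condition there is no replicate check, and no test was made. Before the data were examined the following were fixed: a size rule (at least 2-fold, with the brighter value at or above a floor), the floor (the median over genes of the mean log2 intensity, 8.02, or 260 on the linear scale, 4.68 times the random control set), 26 gene lists, the alternatives and the rule for named genes. That rule took, for each treatment against PBS, the 10 genes with the largest difference each way whose probe sets all had the same sign, up to 4 genes of each list at least 2-fold different, and 10 inflammatory genes at whatever value. Between stimuli it took 5 genes each way. Symbols of uncharacterised type were left out of the first part. Some genes that the rule selects are not reported here. Chosen after the data had been seen were the limit for near background, 2 times the random control set on the same array, the direct comparison of lists between stimuli, a further list of 51 NF-κB target genes from general knowledge, and the leukocyte list after loess centring. Where the dimmer value was near background, the fold was computed against that limit and is given as "at least".

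For each list the median log2 difference was set against 10000 random lists of the same size matched on deciles of mean level, and the percentile describes these arrays only. Overlaps were set beside the count for independent lists and beside 100 rounds of simulated unchanged arrays sharing 1 control, with noise drawn in 20 level bins from the difference between the TNFα and IL1β arrays, the pair that differed least.

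The size rule was tested on simulated data for TNFα minus PBS over 17185 genes, 200 of them changed. It recovered 58.5% of genes changed 2-fold, 92.5% of those changed 3-fold and 99.5% of those changed 4-fold, and called between 57 and 68 other genes. Its noise was Gaussian with the same SD, 0.258, at every level, taken from genes at the floor on the TNFα and IL1β arrays. With noise drawn in level bins, unchanged arrays gave far more calls, 160.9 higher and 159.5 lower per comparison. The smaller number thus understates false calls. Of 100 simulated unchanged lists 2 fell outside the central 95%, and of 100 lists shifted by 0.5 all did. These lists had 20 genes and the same even noise, drawn independently for each gene. Differences of LPS from PBS were wider (SD 0.72 for genes at the floor), so shifts of shorter lists or with LPS are found less surely. Genes that vary together would put more unchanged lists outside.

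The alternatives were no floor, a floor at the 75th percentile, the mean of all probe sets of a gene, loess centring of each pair of arrays, a repeated quantile normalization, the series value table, an offset of 50.9 (the 10th percentile of linear values) added before log2, thresholds of 1.5-fold and 3-fold, lists limited to members at the floor, and lists without their member of largest difference. Added later were all probe sets whether named or not, and named genes without the marker genes of other cell types. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.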

Results

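KYSE410 cells, an established human line of oesophageal squamous cell carcinoma, were exposed for 24 h to phosphate-buffered saline (PBS, the solvent control), tumour necrosis factor α (TNFα), interleukin 1β (IL1β) or lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria). The experiment was set up to find messenger RNAs that respond to inflammatory stimuli. RNA from each of the 4 conditions was measured on 1 single-colour NimbleGen expression array, which gave an RMA intensity for 45033 probe sets, and 17185 named genes could be followed. There were no replicates, so no difference below has an error or a p-value, and the number of arrays limits the precision. Genes are described as higher or lower where 2 arrays differed at least 2-fold and the brighter value reached the floor of 8.02 on the log2 scale. Median intensities were alike, at 259.5 with PBS, 259.3 with TNFα, 258 with IL1β and 245 with LPS. Across genes, the TNFα and IL1β arrays were closest to each other (Pearson r = 0.969), and the LPS array was farthest from the others (r = 0.929 with PBS, 0.926 with TNFα and 0.924 with IL1β). Genes are not independent replicates, so these correlations describe the arrays only.

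The first comparison asked which genes differed after TNFα. Several inflammatory mediators were among the higher genes. CXCL8, the neutrophil-attracting chemokine interleukin 8, had an intensity of 4547 with TNFα against 394 with PBS, 11.5-fold higher. CXCL2, another neutrophil chemokine, was 8.89-fold higher, the T cell and monocyte chemokine CCL5 was 6.11-fold higher, and the cytokine IL6 was 6.12-fold higher. Log2 differences of CXCL2 were alike with TNFα (3.15), IL1β (2.81) and LPS (3.21), as were those of CCL5 (2.61, 2.51 and 2.30). Part of these differences may thus come from the single PBS array. The calcium-binding alarmin S100A8 showed the largest difference among named genes, at least 50.3-fold, and its partner S100A9 was 10.2-fold higher. IRF1, a transcription factor of interferon responses, was 6.96-fold higher, and MMP3, a matrix-degrading stromelysin, was 16.6-fold higher.

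In all, 317 genes were higher and 320 lower with TNFα than with PBS, among 9419 genes at the floor on either array. The interferon-stimulated genes were the clearest group. Of 32 measured members 8 were higher and none lower, and their median log2 difference was 0.62, at the 100th percentile of 10000 random lists matched on level. Examples were MX1, an antiviral GTPase (log2 difference 1.73), IFI6 (1.67) and the guanylate-binding protein GBP2 (at least 2.78-fold). The list of JAK-STAT3 and IL6 family signalling genes had a median of 0.25 at the 98.03rd percentile, with 1 of 18 members higher, the transcriptional repressor BCL6 (at least 3.81-fold). Without that gene the list fell inside the matched range (0.22, 95.71st percentile). Leukocyte markers, fixed as a reference for another cell type, had a median of 0.68 at the 99.99th percentile, with 2 of 14 members higher. In that list the pan-leukocyte phosphatase PTPRC (CD45) was at least 12-fold higher and the Fc receptor FCGR3A 13.7-fold higher. The neutrophil Fc receptor FCGR3B (at least 15.2-fold), the neutrophil alarmin S100A12 (at least 15.4-fold), the phagocyte oxidase subunit CYBB (at least 5.43-fold) and the monocyte lectin FCN1 (12.2-fold) were higher as well. S100A8 and S100A9 are themselves abundant in myeloid cells. The acute phase, complement and antimicrobial list that holds them had 6 of 28 members higher, with a median of 0.15 inside the matched range. The chemokine list also lay inside the range with both cytokines, with 3 of 18 members higher each time, at medians of -0.10 with TNFα and -0.05 with IL1β. Only 5 of the 18 reached the floor in each comparison, and the list limited to members with a mean level at the floor lay above the range with both. That limit uses the mean of all 4 arrays. CXCL2 (7.96 with PBS) and CCL5 (7.61 with PBS) were below the floor with PBS and passed through the treated arrays, so the limited list is no separate support.

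Not all NF-κB target genes differed between the TNFα and PBS arrays. NFKBIA, the inhibitor that restrains NF-κB, had a log2 difference of -0.33, TNFAIP3 (A20) 0.14, BIRC3 -0.11 and CXCL1 -0.30, and CCL20 was near background on both arrays. The NF-κB feedback and survival list had a median of 0.08 with 3 of 20 members higher, namely TNIP1 (1.72), BCL2A1 (1.70) and TNFAIP8 (1.56). TNIP1 and TNFAIP8 were higher by similar amounts with IL1β (1.72 and 1.31) and LPS (1.60 and 1.49). Their differences are thus not particular to TNFα, and part may come from the single PBS array. ICAM1, a leukocyte adhesion molecule, was 2.28-fold higher and the mitochondrial superoxide dismutase SOD2 1.75-fold higher. Among receptors and adaptors, TRAF2 was 7.81-fold higher, TLR4 at least 3.82-fold higher and TNFRSF1B, the second TNF receptor, 3.52-fold lower. In the class I antigen presentation list only TAP1, the peptide transporter (log2 difference 1.96), and PSMB8 (1.37) were higher. The 2 probe sets of PSMB8 differed in direction, and their mean gave -0.11.

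Of 22 matrix proteases and inhibitors 5 were higher and 1 lower with TNFα, with a median of 0.10 inside the matched range. The membrane protease MMP14 was 10.3-fold higher, while the metalloproteinase inhibitor TIMP2 was 4.03-fold lower. Of 23 genes of epithelial-mesenchymal transition 4 were higher and 3 lower. The integrin ITGB1 was 6.91-fold higher and the transcription factor SNAI1 4.72-fold higher. E-cadherin, CDH1, was 5.22-fold lower and tenascin C, TNC, 6.75-fold lower. ITGB1, SNAI1, CDH1 and TNC were also at least 2-fold different in the same direction with IL1β and with LPS. With LPS, for example, ITGB1 was 7.03-fold and SNAI1 6.69-fold higher, and CDH1 had a log2 difference of -2.09. These differences are thus not particular to TNFα, and part of them may come from the single PBS array. SOCS3, a feedback inhibitor of cytokine signalling, was 5.74-fold lower, and the amino acid transporter SLC38A5 at least 13.5-fold lower, the largest lower difference among named genes. Where a gene at least 2-fold different had a second probe set at the floor, 15 of 23 second sets had the same direction and 9 were at least 2-fold different the same way. Over 668 genes with a second set, changed or not, the log2 differences of the 2 sets disagreed with an SD of 0.57. The SD was 0.60 for IL1β and 0.75 for LPS. The TNFα minus PBS difference itself had an SD of 0.52 over genes at the floor. A 2-fold difference in 1 probe set was thus often not repeated by another, and 15836 genes had only 1.

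The second comparison asked the same of IL1β, and many of the same mediators were higher. CXCL2 was 7.01-fold higher than with PBS, CCL5 5.71-fold, CXCL8 5.20-fold and IL6 4.63-fold. S100A8 was again first in size among named genes, at least 16.5-fold higher, and S100A9 was 5.51-fold higher. MMP3 was 6.48-fold higher, MMP14 3.12-fold and ICAM1 3-fold.

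In this comparison 295 genes were higher and 337 lower, among 9427 at the floor. The acute phase, complement and antimicrobial list had a median log2 difference of 0.25 at the 99.34th percentile, with 5 of 28 members higher and none lower. Besides S100A8 and S100A9 they included the complement protease C1R (1.35) and the pentraxin PTX3 (1.09). Leukocyte markers had a median of 0.67 at the 99.99th percentile and 4 of 14 members higher, PTPRC at least 9.67-fold higher, FCGR3A 3.44-fold, the macrophage receptor CSF1R 3.08-fold and CD86 2.32-fold. Interferon-stimulated genes had a median of 0.11 inside the matched range, with 5 of 32 higher and 1 lower. IRF1 was 3.37-fold higher, IFIT2 3.28-fold and TAP1 4.32-fold.

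The NF-κB feedback list again lay inside the matched range with IL1β, with a median of 0.00. BCL2A1 (log2 difference 1.84), TNIP1 (1.72) and TNFAIP8 (1.31) were higher, while NFKBIA differed by -0.20, TNFAIP3 by 0.12, BIRC3 by -0.12 and CXCL1 by -0.23. Among cytokines, IL1B itself was 3.56-fold higher and the receptor antagonist IL1RN 4.07-fold lower. TNFRSF1B was 5.76-fold lower, TNC 5.95-fold lower, CDH1 4.22-fold lower and the laminin-binding integrin ITGA6 4.51-fold lower. The protamine PRM2 was 9.69-fold lower. Of 28 second probe sets 21 had the same direction and 6 were at least 2-fold different the same way.

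**Figure D1:**
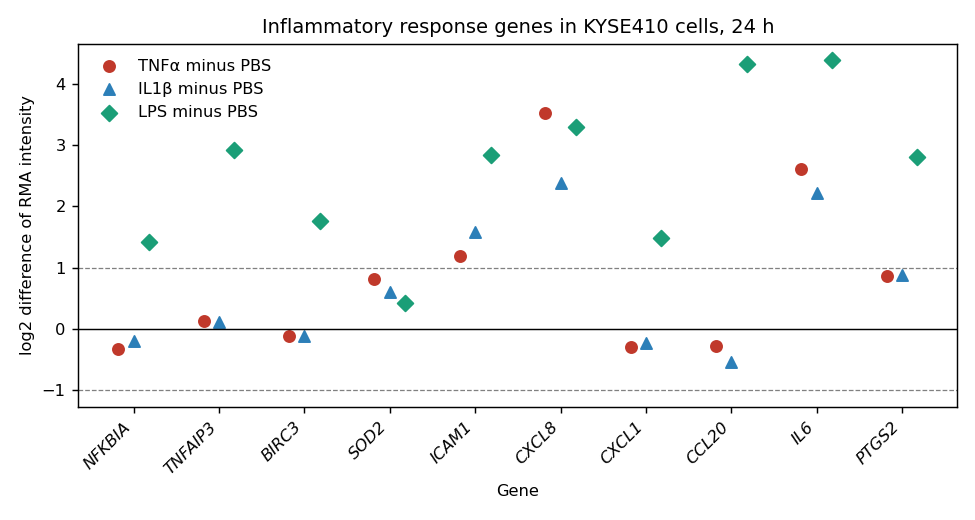
Log2 difference of RMA intensity (vertical axis) of 10 inflammatory response genes chosen before the data were examined (horizontal axis), each treatment minus PBS. Each point compares 1 array with 1 array, without error, and dashed lines mark 2-fold. IL6 and CXCL8 lie above the upper line for all 3 stimuli, while TNFAIP3 and CCL20 do so for LPS, TNFAIP3 at 2.92 and CCL20, near background with PBS, at least 15.9-fold higher.

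The third comparison asked which genes differed after LPS. IL6 had an intensity of 6426 against 308 with PBS, 20.9-fold higher. The chemokine CCL20 was at least 15.9-fold higher, CXCL8 9.86-fold, CXCL2 9.27-fold, CXCL3 at least 5.62-fold and CXCL1 2.80-fold. The NF-κB feedback genes TNFAIP3 (7.56-fold), BIRC3 (3.39-fold) and NFKBIA (2.67-fold) were higher, as were TNFAIP2 (7.5-fold) and ICAM1 (7.18-fold). PTGES, the terminal prostaglandin E synthase, was 8.25-fold higher, and the cyclooxygenase PTGS2 at least 4.01-fold.

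LPS and PBS differed in 854 higher and 718 lower genes, among 9675 at the floor. The LPS array stood apart from all 3 others, with 408 genes at any level at least 2-fold below and 632 above each of them, against 37 to 127 and 103 to 165 for the other arrays. Differences of LPS from PBS thus include whatever else set that array apart. The NF-κB feedback and survival list had a median log2 difference of 0.60 at the 99.96th percentile, with 7 of 20 members higher and 2 lower. One of the lower members, BCL2A1, a survival gene of the BCL2 family, was at least 11.3-fold lower with LPS. Cytokines and growth factors had a median of 0.36 (99.30th percentile), with 7 of 35 higher and 1 lower, among them BMP2 (log2 difference 3.37) and IL1B (2.08). Of 18 chemokines 6 were higher, with a median of 0.39 just inside the matched range (97.10th percentile). Repeated quantile normalization and the offset placed it outside, at the 97.72nd and 98.48th percentiles. Interferon-stimulated genes had a median of 0.41 (99.90th percentile), with 7 of 32 higher and 1 lower, including the restriction factor BST2 (2.44), IRF1 (2.26) and IFIT3 (1.99). TAP1 was 8.06-fold higher.

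Matrix proteases and their inhibitors stood farthest from the matched lists with LPS, with a median of 1.20 at the 100th percentile. Of 22 members 10 were higher and 2 lower. MMP3 was 7.98-fold higher, the urokinase PLAU and MMP14 each 5.53-fold higher, and TIMP3 at least 3.84-fold higher. Squamous differentiation genes had a median of 0.45 (99.75th percentile), with 5 of 29 higher and none lower. They included the cornified envelope proteins CSTA (4.33-fold) and SPRR1B (3.36-fold) and the keratin KRT4 (3.71-fold). The list of basal squamous identity genes lay inside the range (median -0.10), with the basal keratin KRT14 2.38-fold higher, TP63, a transcription factor of the squamous lineage, 2.79-fold higher and ITGA6 2.76-fold lower. The acute phase, complement and antimicrobial list also lay inside it (median 0.17), with 5 of 28 members higher, including SLPI (5.86-fold) and PI3 (4.03-fold).

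Several stress response genes were also higher on the LPS array. The oxidative stress list had a median of 0.45 (98.88th percentile) with 5 of 16 higher, among them the glutathione synthesis enzyme GCLC (2.76-fold) and HMOX1, haem oxygenase (2.74-fold). Without its member of largest difference the median was 0.37, inside the matched range (96.47th percentile). Immediate early genes had a median of 0.37 (98.52nd percentile), with the phosphatase DUSP1 4.75-fold, KLF4 3.41-fold and FOS 3.37-fold higher and SOCS3 4.16-fold lower. The unfolded protein response list lay at the edge of the matched range (0.42, 97.59th percentile), with 3 of 15 members higher and 1 lower. The higher ones included DDIT3 (4.30-fold) and the asparagine synthetase ASNS (4.08-fold). Without its member of largest difference its median was 0.24 (86.91th percentile), and loess, repeated quantile normalization and the offset also placed it inside the range. The cell cycle list lay inside the range, with 1 of 26 members higher, the transcription factor E2F1 (2.34-fold), and 2 lower, among them the proliferation marker MKI67 (3.26-fold). In the cholesterol synthesis list, also inside the range, LSS (lanosterol synthase) was 10.3-fold lower and INSIG1 3.05-fold lower.

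Several of the largest lower differences of named genes with LPS were in transcripts of heart muscle and myeloid cells. MYH6, the α heavy chain of cardiac myosin, had an intensity of 9470 with PBS and 81 with LPS, at least 83.9-fold lower. MYH7, the β chain, was at least 32.5-fold lower, and the cardiac troponins TNNI3 and TNNT2 were 12.3-fold and 11-fold lower. LYZ, lysozyme, was 33.1-fold lower, ALOX5AP, a leukotriene synthesis protein, at least 11-fold lower, and TYROBP, a myeloid signalling adaptor, at least 7.10-fold lower. The TNFα and IL1β arrays had MYH6 at 13.84 and 14.06 on the log2 scale, near the PBS value of 13.21, against 6.34 with LPS. The leukocyte list as a whole had a median of -0.25 with LPS, inside the matched range, with 3 of 14 members lower and 11 neither, and with members limited to a mean level at the floor it fell below the range. Of 88 second probe sets 72 had the same direction and 36 were at least 2-fold different the same way.

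**Figure D2:**
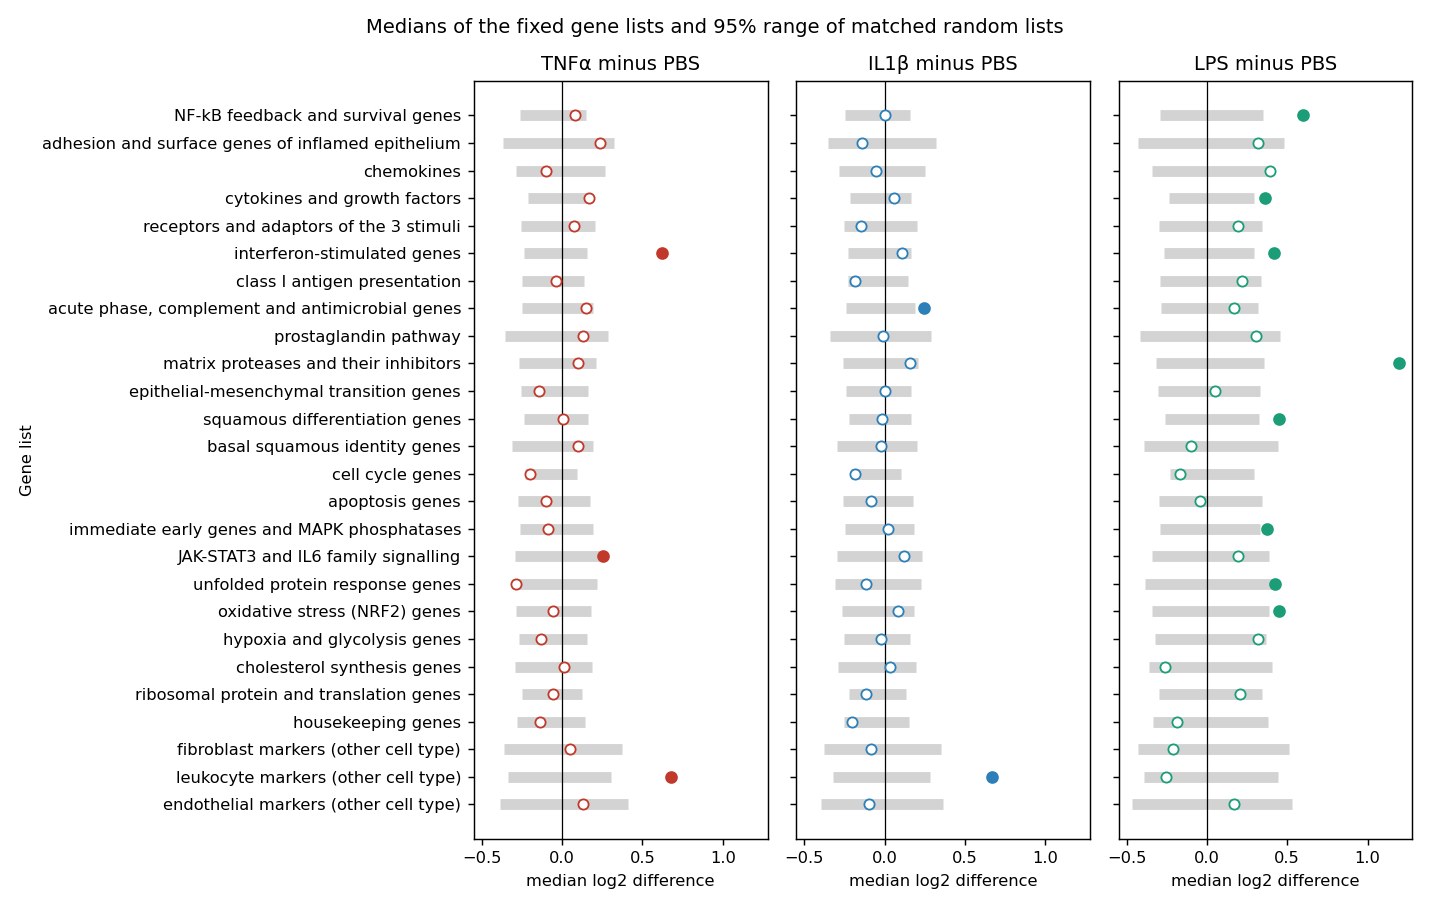
Median log2 difference (horizontal axis) of the 26 gene lists fixed before the data were examined (vertical axis), each treatment minus PBS. Grey bars hold the central 95% of 10000 random lists matched on level, and filled points lie outside them. There are 3 filled points for TNFα, 2 for IL1β and 8 for LPS, all above the bars.

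Over the 26 lists and 3 comparisons 13 of 78 medians lay outside the central 95%, where 3.9 would by chance if the genes of a list varied independently. Genes of a list that vary together would raise that number. The ribosomal, apoptosis, hypoxia and housekeeping lists stayed inside it in each comparison. The housekeeping medians were -0.14 with TNFα, -0.20 with IL1β and -0.18 with LPS. Fibroblast markers had medians of 0.05, -0.09 and -0.21 and endothelial markers 0.13, -0.10 and 0.17, all inside the range, but only 3 or 4 members of either list reached the floor in each comparison, and fibroblast markers with a mean level at the floor fell below it with LPS.

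The stimuli were then compared with each other. TNFα and IL1β differed least, with 173 genes higher and 161 lower with TNFα. S100A12 was 8.06-fold higher with TNFα than with IL1β and the Fc receptor FCGR2A 6.43-fold higher, while the proteoglycan BGN was 5.84-fold lower. Against LPS, TNFα gave 685 higher and 959 lower genes, and IL1β 723 higher and 1024 lower. With loess centring these counts were 792 and 805 for TNFα and 823 and 882 for IL1β. BCL2A1 was at least 36.7-fold higher with TNFα and at least 40.5-fold higher with IL1β than with LPS. CCL20 was at least 15.5-fold and 15.4-fold lower, and the folate receptor FOLR1 25.3-fold and 22.8-fold lower.

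Differences between lists were computed directly as well, a step added after the data had been seen. The NF-κB feedback list was higher with LPS than with TNFα by a median of 0.51 (99.58th percentile of matched lists) and than with IL1β by 0.57 (99.90th percentile). In all 15 of 78 such medians lay outside the matched range. Interferon-stimulated genes were higher with TNFα than with IL1β by 0.34 (100th percentile) and lower with LPS than with TNFα, at -0.26 (2.33rd percentile). Class I antigen presentation was higher with LPS than with TNFα by 0.40 (97.88th percentile) and than with IL1β by 0.49 (99.33rd percentile). The leukocyte list was lower with LPS than with TNFα, at a median of -0.88 (0th percentile), and than with IL1β, at -0.89 (0.01st percentile).

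**Figure D3:**
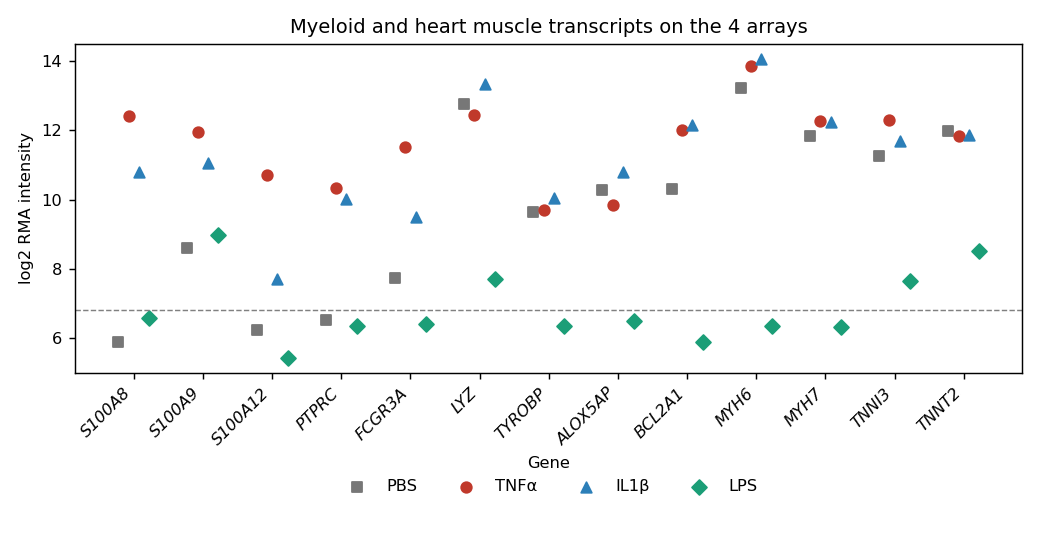
Log2 RMA intensity (vertical axis) of 9 genes known from myeloid or other white blood cells and 4 heart muscle genes (horizontal axis) on the 4 arrays, each point 1 array. The dashed line marks 2 times the random control probe set, at 6.82. S100A8 lies above the line with TNFα and IL1β at 12.41 and 10.80, and MYH6 lies below it with LPS at 6.34.

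Many genes differed from PBS in the same direction with more than 1 stimulus. TNFα and IL1β shared 149 higher genes, against 10.3 for independent lists and 24.3 in simulated unchanged arrays set against 1 shared control. They shared 171 lower genes, against 11.8 and 58.4. TNFα and LPS shared 110 higher and 147 lower genes, and IL1β and LPS 110 higher and 135 lower, against 29.9, 25.4, 27.9 and 26.8 for independent lists in that order. The simulated arrays gave 160.9 higher and 159.5 lower genes per comparison, fewer than any measured one and far fewer than LPS. They thus set no matched value for these overlaps, least of all for those with LPS. Among all 3 stimuli 83 genes were shared as higher, including IL6, CXCL8, CXCL2, ICAM1, TAP1, IRF1, MMP3 and DGKA. As lower, 108 were shared, including SOCS3 and TNFRSF1B. Simulated unchanged arrays sharing 1 control gave 12.2 higher and 39.1 lower on all 3, again from fewer differing genes per comparison. DGKA, a diacylglycerol kinase, was 21.6-fold, 13.3-fold and 21-fold higher, and its PBS value was 3.73 log2 units below the lowest of the other arrays.

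The correlation of log2 differences across genes was 0.75 for TNFα with IL1β, 0.38 for TNFα with LPS and 0.35 for IL1β with LPS. The simulation gave 0.50, which follows from 1 shared control and equal noise on each array, whatever its size. The LPS minus PBS difference had a wider spread (SD 0.72, against 0.52 with TNFα and 0.51 with IL1β), which by itself lowers r. The values with LPS therefore do not mean less likeness than between unchanged arrays. The covariances were 0.200, 0.143 and 0.127, against 0.0671 simulated. All 3 comparisons use the single PBS array, so part of the overlap and covariance may come from that array. Its own noise could not be estimated, since the simulation took its noise from the TNFα and IL1β arrays. Differences that share no array correlated weakly, at r = -0.15 for TNFα minus PBS with LPS minus IL1β and r = -0.20 for IL1β minus PBS with LPS minus TNFα. The remaining pair, added later, LPS minus PBS with TNFα minus IL1β, gave r = 0.06. A response common to all 3 stimuli cancels in a difference between stimuli. A response shared by TNFα and IL1β alone would by itself make the pairs with LPS minus IL1β and LPS minus TNFα negative. These correlations therefore cannot show how much of the overlap comes from the PBS array.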

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

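The leukocyte and NF-κB feedback lists were fixed before the data were examined, while the tests in this part and the lists of heart muscle, neutrophil and monocyte, lymphocyte, red cell and further NF-κB genes were chosen after the patterns had been seen. The test of the further NF-κB list was written before the values of that list were seen.

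The fixed leukocyte list had a higher median on the TNFα and IL1β arrays than on the PBS array, with 2 and 4 of its 14 members at least 2-fold higher at the floor. A level-dependent shift from the normalization would be removed by a loess curve for each pair of arrays. After it the fixed leukocyte list kept medians of 0.66 with TNFα and 0.67 with IL1β, against 0.68 and 0.67 before, which argues against such a shift as the whole cause. The percentiles, 99.99th and 100th after loess, are no separate test, since level-matched random lists carry such a shift as well. For RNA from neutrophils or monocytes as a source, a separate list of 32 neutrophil and monocyte genes, 1 of them also in a fixed list, lay at the 99.98th percentile with TNFα (median 0.39), which goes with that source, and at the 82.7th with IL1β (median 0.09), which leaves it open there, while a lymphocyte list stayed inside the range on both (29.31st and 58.71st percentiles). Members of the neutrophil and monocyte list went both ways, 7 higher and 1 lower with TNFα and 7 higher and 2 lower with IL1β, and ITGB2, picked after its values had been seen, was lower on both (-1.28 and -2.45). LYZ, abundant in these cells, was at 12.76 with PBS, 12.45 with TNFα and 13.34 with IL1β on the log2 scale, though so high a baseline would hide a small share, and a response of the carcinoma cells to the cytokines stays open, untested without replicates.

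Heart muscle transcripts led by MYH6 were high on 3 arrays and lower with LPS, where MYH6 and MYH7 were near background and TNNT2 (8.52) and TNNI3 (7.64) were not. A list of 32 measured heart muscle genes without those first seen had a median LPS minus PBS difference of -0.48, at the 0.04th percentile of matched lists, with 4 members lower and 1 higher, FABP3 (2.43, named after its value had been seen). Those lists carry the wider spread of the LPS array, so the spread alone does not account for it. RNA from heart muscle on the other 3 arrays may be a source, and the list moved as it would need, with the 0.04th percentile. But MYL2, MB, NPPA and CSRP3, abundant in heart and picked after their values had been seen, had a median difference of 0.39. They lay near background or below the floor on all arrays, which cannot exclude it because dim probe sets may simply not report. The list members brightest with PBS, also picked after their values had been seen, fell far less than MYH6 (-6.86). They were ACTC1 (14.13 with PBS, -0.47), TPM1 (11.43, -1.97), TNNC1 (11.25, -1.13) and CKM (11.08, -0.91), while COX6A1 (11.08) was higher, at 0.96. If heart RNA were their only source and absent with LPS, they would have fallen towards background as MYH6 did, so its part stays undecided. Red cell and lymphocyte lists were also low with LPS (medians -0.54 and -0.44, 1.87th and 1.96th percentiles), and whether the LPS array came from another RNA source or culture was not tested; a response to LPS stays open.

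The NF-κB feedback list was higher on the LPS array and inside the matched range on the cytokine arrays. If this came from the wider spread of the LPS array, other NF-κB target genes would lie inside the matched range, and a list of 48 measured genes, none in the fixed lists, had a median of 0.42 at the 99.96th percentile, which argues against the spread alone. The same list had medians of 0.10 with TNFα (97.06th percentile) and 0.11 with IL1β (97.86th), so the cytokine arrays were not without such genes. An exchange of labels between the LPS array and a cytokine array cannot be told apart from a true difference between stimuli, since TLR4, the LPS receptor, had log2 levels of 6.39 on the array labelled LPS, 6.36 with PBS, 6.04 with IL1β and 8.69 with TNFα, which do not settle which agent the cells received. Another RNA source or culture for the LPS array, which stood apart in other lists too, and a stronger or longer response to LPS at the unstated doses both stay open, untested. TLR4 was near background with PBS and with LPS, as was LY96 of the receptor list (5.45 and 6.17), while CD14 was above it (7.36 and 7.72). Dim probe sets may simply not report, so these levels do not decide between them.

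Some genes were at least 2-fold different from PBS in opposite directions, and these differences were not tested. Simulated unchanged arrays gave 0.37 such genes for a pair, a low number because they share 1 control and hold fewer differing genes. Independent lists would give 22.1 for TNFα and IL1β, 55.4 for TNFα and LPS and 55.3 for IL1β and LPS. The counts found were below these. The shared PBS array by itself lowers such counts, so neither figure can show whether there was an excess of opposite genes. TNFα and IL1β had 1 such gene, OGG1. TNFα and LPS had 8, among them BCL2A1 (log2 difference 1.70 with TNFα and at least 11.3-fold lower with LPS) and FOLR1 (-1.44 and 3.21). IL1β and LPS had 12, among them SSR1 (-1.37 and 1.36). OGG1 and SSR1 were chosen after their values had been seen.

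The 26167 probe sets without a gene symbol were outside the comparisons of named genes, and they also differed between arrays. At the same floor 966 were at least 2-fold different with TNFα, 945 with IL1β and 2569 with LPS.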

How the results depend on the processing

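The alternatives of all probe sets and of removing other cell types' markers were chosen after the data had been seen. No paired analysis was possible because each condition has 1 array, and for the same reason no replicate could be left out. Counts for the 6 comparisons are given in the order TNFα, IL1β and LPS minus PBS, TNFα minus IL1β, TNFα minus LPS and IL1β minus LPS, and shared genes in the order of the last 3. Without a floor the counts were 1350, 1389, 2707, 947, 2837 and 3048, the shared genes 567, 488 and 469, and the correlation of TNFα with IL1β 0.645. With the 75th percentile floor they were 204, 205, 696, 74, 710 and 757, the shared genes 128, 111 and 108, and the correlation was 0.797 for TNFα with IL1β and 0.328 for IL1β with LPS. At 1.5-fold they were 1993, 2014, 3735, 1186, 3887 and 4081, with 1006, 786 and 721 shared. At 3-fold they were 227, 215, 503, 86, 453 and 517, with 128, 109 and 103 shared. These shifts follow from admitting more or fewer genes. LPS gave more genes against PBS than either cytokine in each of these settings. Over all probe sets the counts against PBS were 1659, 1630 and 4279, with 43.7% of the LPS ones higher against 54.3% of named genes. The offset gave 207 genes for TNFα minus IL1β, since it shrinks differences of dim genes. Lists limited to members at the floor gave 20 medians outside the matched range instead of 13, and 1 list had too few members there. The lists taken outside were chemokines, at 2.61, 2.38 and 2.30 with TNFα, IL1β and LPS, the acute phase list, at 0.41 with TNFα and 0.58 with LPS, squamous differentiation with TNFα (0.33), class I antigen presentation with IL1β (-0.24), and with LPS the leukocyte (-1.22) and fibroblast (-0.98) markers. It took JAK-STAT3 signalling with TNFα (0.24) and oxidative stress with LPS (0.37) inside. That limit uses the mean of all 4 arrays, so a high value on 1 array helps a gene to pass it. The cause was not tested further. PSMB8 with TNFα reversed to -0.11 with the mean of its 2 probe sets, which disagree.

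The other 71 values of this kind stayed within 1.5 times or, for correlations, within 1 bootstrap SD. They included all under loess, repeated quantile normalization, the mean of probe sets and the series table. The series table held identical intensities, so its 13 values could not move and are no support. Without other cell types' markers the counts against PBS were 623, 618 and 1550. No scaling moved the share of higher genes by 10 points or the median gene by 0.1 log2. Of the differences of named genes 1318 stayed on their side of 2-fold, 15 fell below it and 1 passed it, and 506 list medians were the same against 37 moved. Among the unchanged ones, 267 gene differences and 78 list medians came from the identical series table and could not have moved. The floor does not enter list medians or single differences, so its alternatives could not change them. Signal over background limits dim genes: 72.0%, 71.4%, 70.7% and 71.0% of genes exceeded 2 times the random control set with PBS, TNFα, IL1β and LPS.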

Other observations

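A few further genes differed from the single PBS array with more than 1 stimulus. VEGFC, a lymphatic growth factor, was 3.22-fold higher with TNFα, 2.67-fold with IL1β and 3.56-fold with LPS, and IL1RN was lower with TNFα (log2 difference -1.96), IL1β (-2.02) and LPS (-1.16). TRAF2 was higher with all 3 stimuli (log2 differences 2.97, 1.54 and 1.64). The sterol desaturase SC5D was lower with both cytokines (-1.65 and -1.88), as was PDK1, a kinase that limits pyruvate oxidation (-1.19 and -1.30).

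With LPS 3 of 16 genes of the hypoxia and glycolysis list were higher, NDRG1 by 3.54-fold, ANKRD37 by 3.73-fold and ADM, adrenomedullin, by 2.57-fold, although the list lay inside the matched range (median 0.32, 95.33rd percentile). Vimentin, VIM, was 4.99-fold lower and N-cadherin, CDH2, 4.53-fold higher, both members of the epithelial-mesenchymal transition list, whose median was 0.05. CDH2 was also at least 2-fold higher with TNFα and with IL1β. VIM was also lower with TNFα (log2 difference -1.07) but not with IL1β (0.08). With LPS, S100P, a calcium-binding protein, was 13.8-fold higher and MACC1 at least 4.88-fold lower.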
